A study of Mus musculus with 2 samples.

How the data were processed

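The series holds 1 ELAVL2 RIP sample and 1 input sample from newborn mouse ovary. Per the labels' protocols, 100 ovaries were homogenised, the antibody (5 ug) was bound to protein G beads and incubated with the lysate for 6 hours, and 5% of the lysate was kept as input. RNA was amplified and made into stranded libraries that were sequenced as single reads of 36 bases. Per the file headers, the redundant rate was 0.92 for the RIP and 0.91 for the input. Removed tags can be amplified copies of a molecule or separate molecules of an abundant RNA, which these files do not tell apart.

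Per the submitters' processing notes, CASAVA 1.8.2, FastQC 0.11.2, TopHat2 2.0.8b and MACS2 2.1.0.20140616 were used with the mouse build mm10. Per the file headers, the authors pooled 3 RIP lanes and 3 input lanes and called peaks with MACS2 without a shift model, with tags of 36 bases extended to 50 bp, 1 tag kept per position and strand, a q cutoff of 0.05, an effective genome size of 1870000000 bp, local background windows of 1000 and 10000 bp and the larger library scaled to the smaller. The caller was made for DNA: it takes no account of splicing, strand or transcript abundance beyond the local input. A spliced transcript can therefore give several genomic peaks, overlapping or antisense genes cannot be told apart, and 1 tag per position limits the pileup of abundant RNAs.

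The signal in the peak list is the pileup of RIP tags at the summit, as the authors deposited it. The fold enrichment is a ratio, per the file headers of the authors' peak caller, of RIP pileup to scaled local input with a pseudocount of 1 on both. The -log10 p and -log10 q of each peak were deposited by the authors and were used only to describe, rank and filter peaks within the list. The authors' deposited gene table pairs peaks with Ensembl genes, as overlapped or nearest. How it was made is not given in the sources used here. It held 85730 rows, of which 42176 were exact repeats and were dropped, leaving 43554 pairs.

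The input level of each peak was computed from pileup and fold. It is the peak caller's local background, which can come from the 1000 or 10000 bp windows or the genome-wide background. It is therefore not a count of input tags at the summit. The Poisson -log10 p recomputed from this level differed from the deposited one by at most 5.62e-05. The input scaling factor was 0.708, so 1 input tag equals a level of 0.708. Symbols of 9628 of 11969 genes (80.4%) matched the reference gene table of GRCm38.p6, the same assembly as mm10, directly or by an unambiguous older symbol, and the bodies of 99.8% of matched genes overlapped in both. Lists were counted over all their members. Percentiles come from 10000 random lists of the same size, drawn within 10 strata of gene length from 49997 reference genes. On simulated peaks that depended on gene length alone, 6.0% of 200 lists of 50 long genes fell outside the central 95% range with length matching, and 47.5% rose above it without. All lists (100%) whose members were 2.5 times as likely to hold a peak did so. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used. Shares have exact Clopper-Pearson 95% intervals, which cover counting only and not the spread between experiments.

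Genes were named by a rule fixed before the data were examined: Elavl2, the other Elavl genes and Ddx6; the 10 genes with an approved symbol with the largest fold at a pileup of at least 20; the 10 with the largest -log10 q; the 5 with most peaks; and the 3 members of each gene list with the largest best fold. Some genes that the rule names are not reported here. Further list members with a peak inside them are named as examples, chosen after their values were seen. Alternatives fixed in advance were stricter q, fold and pileup thresholds, merging of neighbouring peaks, peaks paired with 1 gene only, overlap with reference gene bodies, other backgrounds for the random lists and a fold without the pseudocount. Counting only genes that a peak overlaps was chosen after seeing that the table also holds nearest genes.

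A sequence and exon annotation were not used here. The planned placement of summits in exons, introns and untranslated regions was therefore replaced by the location columns of the authors' table, and the planned search for U-rich sequence was left out. No p-value across genes is given, since genes are not replicates of 1 RIP and 1 input sample.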

Results

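ELAVL2 is an RNA-binding protein of the ELAVL (Hu) family, and the series measured which RNAs came down with an antibody against it from newborn mouse ovary. In RNA immunoprecipitation followed by sequencing (RIP-seq), an antibody pulls a protein from a lysate together with the RNA bound to it, and that RNA is compared with the RNA of the whole lysate. There was 1 ELAVL2 RIP sample and 1 input sample, the input being 5% of the starting lysate, and the labels give 100 newborn ovaries as homogenised. With no control pulldown among the samples, RNA bound to ELAVL2 cannot be told apart from RNA retained in another way. The RIP had 172711531 aligned tags in 3 pooled lanes and the input 210270620 in 3 pooled lanes. Whether the lanes of a sample held 1 library or several is not given in the sources used here. After tags at the same position and strand were reduced to 1, 13787676 RIP tags (7.98%) and 19479946 input tags (9.26%) were left for peak calling. With 1 sample per arm and peaks called on pooled lanes, no value below has a replicate check, and each peak's fold enrichment, pileup (the number of overlapping tags at the summit) and -log10 q are the authors' own values from that comparison.

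The first comparison asked which transcripts were enriched in the ELAVL2 RIP over input, beginning with Elavl2, its family and Ddx6. Elavl2 itself (chromosome 4, 91250763 to 91400785, mm10) was overlapped by 13 peaks. Its largest fold enrichment, 6.62, was at 91311572 to 91311630 with a pileup of 15, and its largest -log10 q, 12.9, was at a peak over the annotated 3' end with a fold of 3.34 and a pileup of 71. Elavl1, which encodes the widely expressed family member HuR (chromosome 8, 4284782 to 4325100), was overlapped by 14 peaks, 10 of them within 5 kb of the 3' end. Its best fold was 5.37, and its peak at 4288365 to 4288591 had a fold of 4.75 and a -log10 q of 20.4. Ddx6, the RNA helicase of P-bodies (chromosome 9, 44604892 to 44640731), was also overlapped by 14 peaks, with a best fold of 4.34 at a pileup of 31, and 8 of them lay within 5 kb of the 3' end. The neuronal family members had fewer peaks with higher folds: Elavl4 had 5 peaks and a best fold of 8.49 at a pileup of 12, and Elavl3 had 1 peak with a fold of 7.02 at a pileup of 17. At a pileup of at least 20 the best fold of Elavl2 was 3.34, and Elavl3 and Elavl4 had no peak. From peaks paired with exactly 1 gene, Elavl2 and Elavl3 had no peak, and the best fold of Elavl1 was 2.44. The peaks of Elavl1, Elavl2 and Elavl3 given above each overlapped only 1 gene and were also paired with a gene outside them. The best peaks of Elavl4 and Ddx6 were paired with no other gene.

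**Figure D1:**
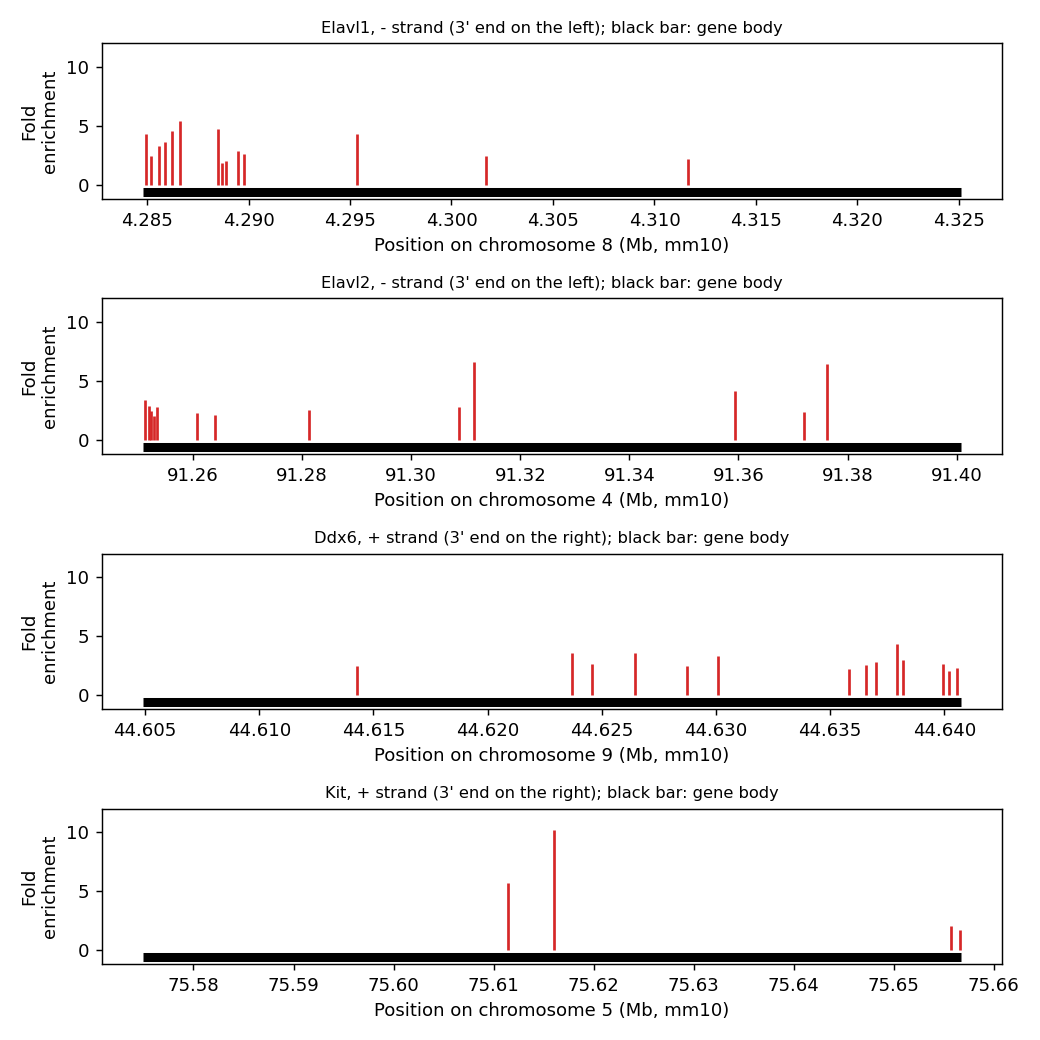
Peaks that overlap Elavl1, Elavl2, Ddx6 and Kit, drawn at their midpoint in Mb on mm10 (x axis) with their fold enrichment (y axis); the black bar is the gene body in the authors' deposited table. In Elavl1 10 of 14 peaks lie within 5 kb of the 3' end, while the Kit peak with the largest fold, 10.2, lies inside the gene body away from that end.

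Among genes with an approved symbol and a pileup of at least 20, the largest folds inside a gene body were 15.0 in Gmds, an enzyme of GDP-fucose synthesis (chromosome 13, 32157576 to 32157746), 14.7 in Anks1b, 14.1 in Rab11fip1, 13.5 in Adtrp, 13.1 in Speer4f2 and 12.9 in Rnf180. The Rab11fip1 peak overlapped 2 genes, and Speer4f2 belongs to a multi-copy family, so both names are uncertain. From peaks paired with exactly 1 gene, Rab11fip1, Adtrp and Rnf180 had no peak, and the best fold was 7.36 in Anks1b and 5.86 in Speer4f2. The best peaks of Adtrp, Rnf180, Anks1b and Speer4f2 each overlapped only 1 gene and were also paired with a gene outside them. The remaining 4 of these 10 genes were named through peaks outside them: Gtf3c3 (fold 15.8, 5867 bp upstream), Gpsm2 (15.6, 1790 bp upstream), Sgpp1 (14.1, 6099 bp upstream) and Pou4f1 (12.9, 124608 bp downstream). Inside its own body Pou4f1 was overlapped by 8 peaks (best fold 7.83), Gtf3c3 by 1 (2.41), Sgpp1 by 1 (3.39) and Gpsm2 by none.

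The largest -log10 q of any peak was 31.1, at a gene without a symbol in the table. Among genes with an approved symbol, Tubb3, a neuronal beta-tubulin, ranked first by -log10 q with 27.9 at its 3' end (chromosome 8, 123421750 to 123421981, fold 11.5, pileup 43), at a peak that overlapped 2 genes. Lsm12 reached 27.7 (fold 8.54), Tfap4 27.3 (fold 5.61), the splicing regulator Rbfox2 25.4 (fold 6.03), Rab11fip1 24.6 and the phosphatase subunit Ppp4c 22.7 (fold 4.38, pileup 87). The other 4 of the 10 were named by peaks outside them: Tmem101 and Srl shared the peaks inside Lsm12 and Tfap4, and Gpsm2 and Gtf3c3 were those given above. From peaks paired with exactly 1 gene, Tubb3, Rbfox2, Rab11fip1, Srl and Fgfr2 had no peak, and the best fold was 3.33 in Lsm12, 3.35 in Tmem101 and 5.38 in Tfap4. The peaks given above for Rbfox2, Lsm12 and Tfap4 each overlapped only 1 gene. The most peaks were paired with Fgfr2 (49), the RNA-binding protein gene Celf2 (46), Camta1 (38), Pcdh15 (38, of which 35 overlapped it) and Bbx (35). The Fgfr2 body in the authors' deposited table spans 2961 kb, against 104 kb in the reference annotation, and 0 of the 49 peaks lay in the shorter body. Within the reference bodies Celf2 held 41 peaks, Camta1 21, Pcdh15 35 and Bbx 35.

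In all, 28332 peaks were called, with a median length of 79 bp (50 to 2030). Their median fold enrichment was 3.59 (quartiles 2.58 and 5.11, range 1.53 to 18.7), their median pileup 24 and their median -log10 q 4.23. The authors' deposited table paired 28179 peaks with 11969 genes. Of these genes, 6158 were overlapped by a peak, and 5811 were only the nearest gene to a peak outside them. Among overlapped genes, 5140 were protein-coding in the reference, which is a symbol-based match, and 357 were long noncoding RNA genes. Exactly 1 peak overlapped 2176 genes, and 5 or more overlapped 1705. Requiring overlap lowered the number of genes by more than 1.5 times, so both counts are given for the gene lists.

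The second comparison asked whether gene groups relevant to the ovary and to RNA regulation held peaks more often than other genes. Genes of P-bodies and mRNA decay did: 41 of 50 were paired with a peak and 38 were overlapped by one, against a median of 12 overlapped (central 95% range 6 to 17) in 10000 random lists matched on gene length. They included Patl2, an oocyte translational repressor (best fold 9.61, at a peak overlapping 2 genes), the deadenylase subunit Pan3 (8.77), the exonuclease Xrn1 (8.15) and Cnot6l, a CCR4-NOT deadenylase with 31 peaks (6.07). Lsm14b, second by fold in the list, was named by a peak 4110 bp upstream (9.56), and its own body held 3 peaks with a best fold of 2.50. The germline and translational RNA-binding proteins stood as high, with 43 of 56 paired and 42 overlapped (random median 16, range 10 to 22). Celf2 had a best fold of 11.7, Lin28b, an inhibitor of let-7 maturation, 10.5, and the meiotic helicase Ythdc2 7.36. Both counts were above the random range, at the 100.0th percentile. At a pileup of at least 20, the best fold was 4.66 in Pan3, 4.65 in Celf2, 6.29 in Lin28b and 6.26 in Lsm14b. From peaks paired with exactly 1 gene, Patl2 and Pan3 had none, and the best fold of Celf2 was 7.61. The best peaks of Pan3 and Celf2 overlapped only 1 gene and were also paired with a gene outside them.

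Of the oocyte and follicle formation genes, 14 of 29 were paired and 10 overlapped (random median 4, range 1 to 8). Kit, the receptor tyrosine kinase of oocytes, had a best fold of 10.2 at a pileup of 13, Tbpl2 9.36, Taf4b 6.58 and the growth factor gene Bmp15 5.13. Uchl1 was named by a peak 8745 bp upstream (9.02) and had a best fold of 1.96 inside. Of the meiosis genes, 19 of 36 were paired and 18 overlapped (random median 9, range 4 to 14), among them Hormad1 (9.95) and Hormad2 (8.04), which encode proteins of the meiotic chromosome axis, and Spo11 (7.31), which makes meiotic double-strand breaks. Tex12 was named by a peak 5520 bp upstream (11.3), with 5.37 inside. Against protein-coding random lists alone the overlapped count of the oocyte list was at the 97.47th percentile and that of the meiosis list at the 99.3rd, and the paired counts were at the 98.9th and 94.6th. At a pileup of at least 20, the best fold was 2.05 in Kit, 3.90 in Tbpl2, 1.97 in Hormad1 and 1.77 in Hormad2. From peaks paired with exactly 1 gene, Uchl1 had none.

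Among markers of somatic cells, 6 of 27 granulosa and pregranulosa genes were paired and 2 overlapped (random median 5, range 2 to 9): Fshr, the FSH receptor (7.31 at a pileup of 9), and Cdkn1b (2.19). Inhba and Gata4 were paired only with peaks outside their bodies in the authors' deposited table. The best Inhba peak was 185025 bp away and the Gata4 peak 32528 bp away, while the reference body of Inhba held 1 peak. Of 17 stromal genes 2 were paired and 2 overlapped, Maf (4.88, at a peak overlapping 2 genes) and Ptch1 (1.89). Of 10 endothelial genes 2 were paired and 1 overlapped, Tek (3.97), while Cdh5 was paired with 4 peaks outside it, the best of them 569637 bp away. Of 11 epithelial and mesonephric genes 3 were paired and 2 overlapped, Cdh1 (4.03) and Epcam (1.77). Upk3b was paired only with 2 peaks outside it, the best of them 17637 bp away. None of the 12 erythroid and none of the 10 immune genes was paired with a peak. Together, 13 of 87 somatic genes were paired and 7 overlapped (random median of overlapped genes 15, range 9 to 22), against 33 paired and 28 overlapped of 65 in the oocyte and meiosis lists (13, range 8 to 19). Each somatic list alone lay inside its random range drawn from all genes. For overlapped genes that range began at 0 in every somatic list except granulosa. For paired genes it began at 0 in the erythroid, immune and epithelial lists. No count could fall below such a range. Against protein-coding lists the overlapped granulosa count was at the 0.79th percentile, and the paired immune and stromal counts were at 1.08 and 2.38. The paired somatic count together was at the 1.41st percentile with length matching and at the 15.9th, inside the range, without it. From peaks paired with exactly 1 gene, Ptch1, Cdh1 and Upk3b had none, and the best fold of Maf was 2.39. The best peaks of Ptch1 and Cdh1 overlapped only 1 gene and were also paired with a gene outside them.

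The remaining lists were also fixed before the data were examined. Of 27 PI3K, FOXO3 and mTOR signalling genes, 17 were paired and 15 overlapped (random median 8, range 4 to 13), with best folds of 10.2 in Kit and 5.76 in Foxo1. That Foxo1 peak overlapped 2 genes. The best fold of Foxo1 was 4.68 from peaks paired with exactly 1 gene and 3.90 at a pileup of at least 20. Of 30 known targets of ELAVL proteins in other cells, 14 were paired and 13 overlapped (5, range 2 to 9). Against protein-coding lists the paired count was at the 95.4th percentile, inside the central 95% range, and the overlapped count at the 99.3rd, above it. Elavl4 had a best fold of 8.49 and Bcl2 of 6.32, while Fos was paired only with a peak 15611 bp downstream. Of 44 translation factors, 18 were paired and 13 overlapped (6, range 2 to 11), but against protein-coding lists these counts were at the 94.3rd and 92.5th percentiles, inside the central 95% range. They were led by Eif4e3 (7.61, and 2.75 at a pileup of at least 20) and Eif4g3 (6.72), with Eif3m named by a peak outside it (8.21, against 4.03 inside). Overlapped counts lay inside the random range for housekeeping references (3 of 15, Tbp 4.38, Ywhaz 3.73 and Hprt 2.73), cytosolic ribosomal proteins (5 of 85), respiratory chain genes (12 of 118, Ndufaf5 7.03), histones (1 of 63, Hist1h1c 1.94) and nuclear long noncoding RNAs (0 of 11). For the housekeeping, histone and noncoding RNA lists that range began at 0, so their overlapped counts could not fall below it. With paired genes, 18 ribosomal (range 4 to 16) and 32 respiratory chain genes (range 11 to 27) lay above the range and 1 histone gene (range 2 to 11) below it. Against protein-coding lists the ribosomal and respiratory chain counts were at the 85.1th and 92.8th percentiles, inside the central 95% range. The paired counts of 4 housekeeping genes and 1 noncoding RNA gene were inside their ranges, which also began at 0. From peaks paired with exactly 1 gene, Eif4e3, Tbp, Ndufb11 and Rpl9 had none, although the best Tbp peak overlapped only 1 gene. The ribosomal genes Rpl10l and Rpl9, the respiratory chain genes Ndufb11 and Cox7a1, and Snhg11 were paired only with peaks outside them. The percentiles describe these 2 samples: they do not take expression into account, and expression of genes without peaks was not analysed here.

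**Figure D2:**
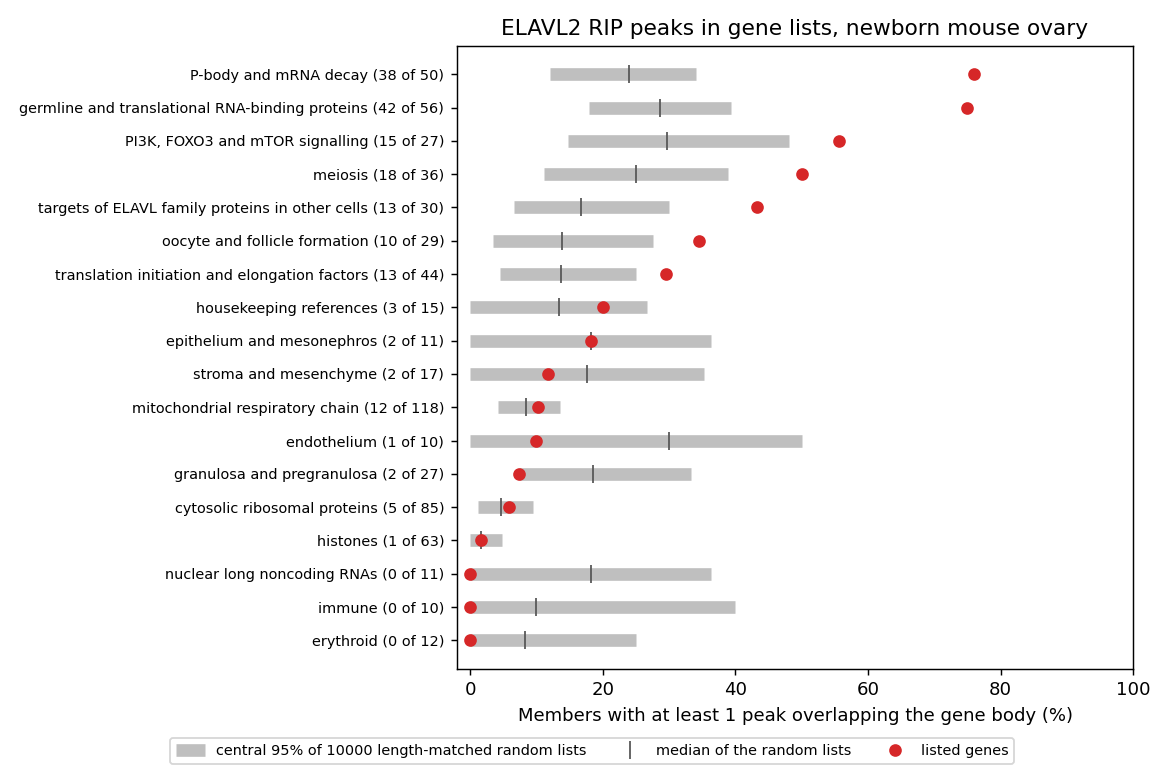
Share of each list's members with at least 1 peak overlapping the gene body (x axis, %; red points), for each gene list (y axis, with counts); grey bars are the central 95% range and ticks the median of 10000 random lists of the same size matched on gene length. P-body and RNA-binding genes (38 of 50 and 42 of 56) lie to the right of the random range, and the erythroid and immune lists have no member with a peak.

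The third comparison asked where in and around genes the enriched RNA came from. A gene body was overlapped by 21215 of 28332 peaks (74.9%, exact binomial 95% interval 74.4 to 75.4, which covers counting only), and 19371 overlapped exactly 1. Peaks outside genes were a median of 14632 bp from the nearest paired gene. Their median fold was 4.68 with a median pileup of 13, against 3.26 and 28 for peaks in genes. Of the 19371 peaks in exactly 1 gene, 9032 (46.6%, 45.9 to 47.3) had their summit in the last 10% of the gene body and 907 (4.68%, 4.39 to 4.99) in the first 10%. The position moved with the input level, which is the peak caller's local background and not a tag count at the summit. Of 2600 such peaks with a level of at most 1 input tag, 15.7% (14.3 to 17.1) lay in the last 10%. Of 16771 above that level the share was 51.4% (50.7 to 52.2). The median gene length of these classes also differed, 112 kb against 49.0 kb, so input level and gene length are not told apart here. Exons and untranslated regions were not used here, so these positions are along whole gene bodies with introns, and the called peaks carried no strand.

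**Figure D3:**
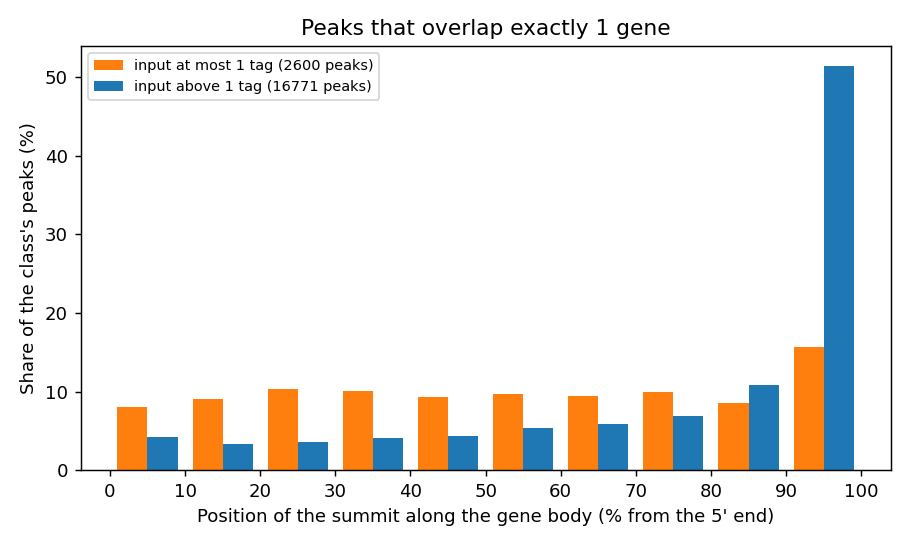
Share of peaks (y axis, % of the class) by summit position along the gene body from the 5' end (x axis, %), for peaks overlapping exactly 1 gene. Orange marks peaks with an input level of at most 1 tag (2600 peaks) and blue those above it (16771 peaks). The last 10% holds 51.4% of peaks above that level and 15.7% of peaks at or below it.

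The fourth comparison set enrichment against the input level, since that decides which transcripts could show a high fold. Genes such as Celf2, Kit, Pan3, Hormad2 and Fshr had their best fold where the input level was the genome-wide background of 0.369 tags, while Ppp4c had its peak at an input level of 19.1. From the lowest to the highest quintile of input level, the median fold was 5.85, 4.97, 3.60, 2.76 and 2.14. Without the pseudocount of 1 in the fold these medians were 15.5, 7.06, 4.06, 2.91 and 2.20. In the highest quintile no peak exceeded a fold of 4.47, and in the lowest the largest was 18.7. Because 1 tag per position and strand was kept and tags were extended to 50 bp, a pileup could not exceed 100, and the highest seen was 97. At the background level the lowest fold called was 3.65, so folds of genes at different input levels are not on an equal footing.

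**Figure D4:**
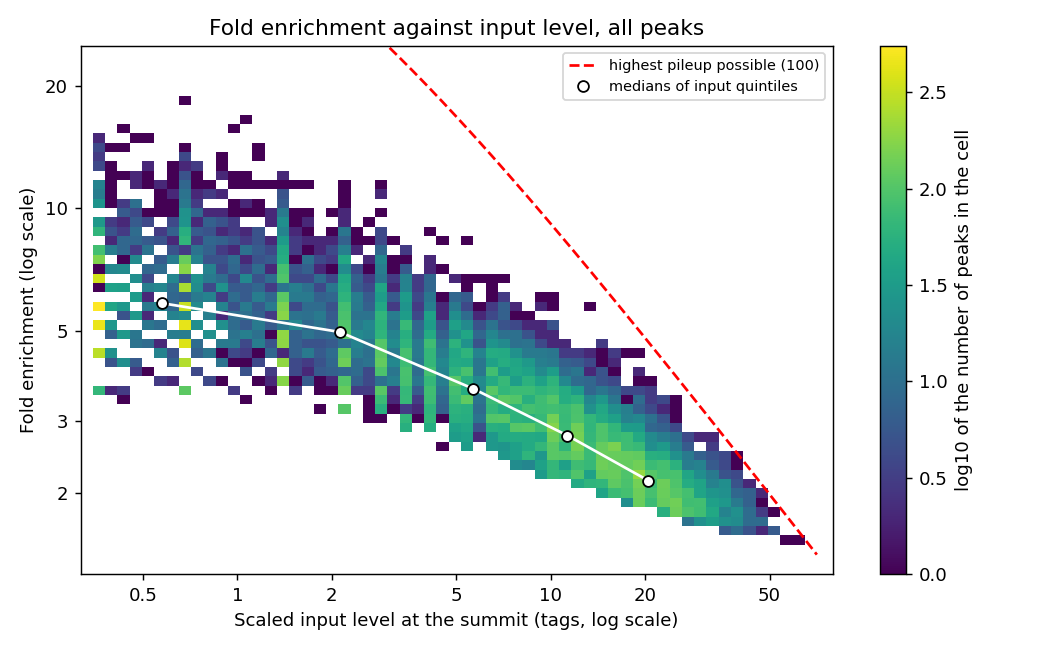
Fold enrichment (y axis, log scale) against the scaled input level of the peak in tags (x axis, log scale) for 28332 peaks. The input level is the peak caller's local background, not a tag count at the summit. Colour gives the log10 number of peaks per cell. White points are medians of the 5 input quintiles and the dashed line is the fold at the highest possible pileup of 100. The medians fall from 5.85 to 2.14.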

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

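Of the tests in this part, that of the input level was chosen after its result was seen. The prediction for gene length was written after the list counts had been seen and before the comparison with matched lists.

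Peaks were called on chromosome Y although the tissue was ovary: 41 peaks, with a median pileup of 9 and a median fold of 5.11. Reads placed at several copies may account for part of them. A twin of equal length, summit offset, pileup and fold elsewhere was found for 23 of the 41 (56.1%), against 26.1% (range 14.6 to 39.0) expected from autosomal peaks of similar pileup and length. Male tissue in the sample stays open: of 5 single-copy genes active in males, Usp9y held 1 peak (1386367 to 1386437, pileup 8, fold 3.73), and the other four held none. Male tissue predicted at least 1 peak inside these genes, and the Usp9y peak met that prediction. This peak had no twin of the kind counted above, but whether it holds reads of its X-linked relative was not tested. No other biological explanation was tested.

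A further 153 peaks lay on 15 unplaced contigs and entered no gene comparison, since all of them were paired with no gene. Their median fold was 4.55 and their highest 9.59.

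The germ cell and RNA-regulation lists together held peaks in 117 of 171 members (68.4%) and the somatic lists in 13 of 87 (14.9%), a difference of 53.5 percentage points. Taken apart, the RNA-regulation lists had 84 of 106 (79.2%) and the germ cell lists 33 of 65 (50.8%). The pooled difference is therefore not one between germ cell and somatic genes alone. Length-matched random lists gave differences of at most 26.0 points (central range -4.23 to 17.2), which argues against gene length as the whole explanation. Counting overlapped genes only, 108 and 7 members held a peak, a difference of 55.1 points against at most 24.7 in random lists. The input level of the genes cannot be told apart from binding, because the files give no input level for the 74 somatic members without a peak. Low abundance of somatic RNAs, few somatic cells or no ELAVL2 in those cells stay open. Whether ELAVL2 in germ cells gives the difference is a hypothesis that was not tested.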

How the results depend on the processing

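Of the alternatives below, overlap of the peak with the gene (also with reference bodies or with input above 1 tag for the lists) was chosen after seeing the data. The cause of these changes was not tested, except that stricter thresholds keep fewer peaks by construction. The number of peaks was 10609 and 1542 at a -log10 q of at least 5 and 10, 18018 and 7401 at a fold of at least 3 and 5, 16515 at a pileup of at least 20, and 15163 after merging within 1000 bp. At a pileup of at least 20 the median fold was 2.74. Genes with a peak numbered 6891 and 1727 at the q thresholds, 5472 at a fold of at least 5, 7572 at a pileup of at least 20, 5482 from peaks paired with 1 gene, 6752 by overlap with reference bodies and 6158 by overlap in the authors' table.

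For the P-body list 8 members were left at a -log10 q of at least 10 and 18 at a fold of at least 5. From peaks paired with 1 gene only (single-gene peaks) 20 were left. For the RNA-binding list these were 15, 22 and 21, and for the oocyte and meiosis lists together 8, 18 and 19. The somatic lists kept 7 members at a -log10 q of at least 5, 2 at 10, 5 at a fold of at least 5, 8 at a pileup of at least 20, 7 with single-gene peaks, 7 by overlap, 8 by reference bodies and 6 by overlap with input above 1 tag. The percentile of the oocyte and meiosis lists was 99.7 against protein-coding lists and 99.9 by overlap with these. That of the somatic lists, 1.41 in the main setting, was 15.9 without length matching, 0.355 by overlap, and 0.005 against protein-coding lists both for paired and for overlapped genes. The share of peaks overlapping a gene was 72.1% and 67.7% at the q thresholds, 67.0% and 57.5% at the fold thresholds, and 85.2% at a pileup of at least 20. Without the pseudocount the median fold was 2.20 in the highest quintile of input and 15.5 in the lowest, against 2.14 and 5.85 with it. Counts were taken as kept within 1.5 times the main count, shares, medians and percentiles within their 95% interval, and best folds of single genes only when equal. By these measures 31 other values of these results were kept, and of those of single genes and smaller lists 180 were kept and 114 moved.

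Exon overlap, majority placement, precedence of coding exons and all U-rich motif settings were not run, because sequence and exons were not used here. Depth limits rare RNAs: at the background input level a pileup of 4 is the least that was called. Abundant RNAs are limited by keeping 1 tag per position and strand, since the highest possible pileup of 100 passes only up to an input level of 67.9. No paired analysis was possible because each arm has 1 sample and the peaks come from pooled lanes.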

Other observations

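Of the values in this part, the grouping of genes by symbol was chosen after seeing the data. Protein-coding genes were grouped by the letters that open their symbol, and 102 such families had at least 20 members. Among them, 11 held overlapping peaks in more members than the central 95% range of length-matched protein-coding lists, and 9 in fewer. By the ratio to the random mean, symbols opening with Arl came first with 13 of 27, then those with Zbtb with 22 of 41 (Zbtb46 8.51), Rbm with 21 of 38 (Rbm10 8.03, Rbm15 7.93), Taf with 12 of 24 (Taf2 9.50) and Med with 15 of 30 (Med14 10.2). Symbols opening with Ube had 24 of 42 and those with Fbxo 18 of 36. Families below their range included Vmn (5 of 353), Krt (1 of 53) and Rhox (0 of 33). Chance alone places some of 102 families outside a 95% range.

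Peaks with an input level of at most 1 tag numbered 5310, of which 2766 (52.1%, 50.7 to 53.4) overlapped a gene. Among the 23022 with a higher level the share was 80.1% (79.6 to 80.7). Priming at the 3' end of mature mRNA may place tags near gene ends, and such priming predicts at least as large a share of these peaks in the last 10% of the gene body as among peaks with more input. The share was 15.7% (14.3 to 17.1) against 51.4% (50.7 to 52.2), but this excludes nothing: the peaks were picked by their input, and the share rose from 18.6% to 67.1% over the quintiles of input, so the bound set in advance was wrong. A twin of equal length, summit offset, pileup and fold was found for 28.5% of peaks with an input level of at most 1 tag. Among peaks with a higher level the share was 3.03%. The median pileups of these classes also differed, 8 against 29, so the shares alone do not decide on reads placed at several copies. Such reads, priming at the 3' end, unspliced RNA, unannotated transcripts, genomic DNA and chance pile-ups of few amplified tags stay open, since intron and exon were not used here.

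Of 214 peaks with a fold of at least 10, 124 (57.9%, 51.0 to 64.6) overlapped a gene and 90 did not.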
